A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

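RNA with a poly(A) tail was compared on 9 dual-channel arrays of Saccharomyces cerevisiae cells deleted for both YPK1 and YPK2 and grown without leucine. The Cy3 channel held cells with a WT kinase on a plasmid, and the Cy5 channel held AS cells on 8 arrays and WT Ypk2 cells on the remaining array. The Ypk1 series received 2,3-DMB-PP1 at 0.5 µM and the Ypk2 series 3-MB-PP1 at 1 µM, each for 0, 15, 30 or 60 min.

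The values deposited by the authors are log2 ratios of the 2 channels of an array. The scale was read from the values: taken as log2, each corresponds to a ratio on a grid of 0.001, which holds for at most 26.3% of values if they are taken as log10. How the ratios were normalized, and which scanner and array design were used, is not stated in the sources at hand; array medians ranged from −0.52 to 0.23, so the ratios were not centred on the median. The direction, Cy5 over Cy3, was read from the WT array, where YPK2 was deposited at 5.34 and YPK1 at −4.47, and it is assumed for the other 8 arrays. The values used here hold no intensities, so a dye bias that depends on intensity could not be checked, and random lists could not be matched on expression.

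The table held 6268 features, 5777 of which were matched to a gene of the R64 annotation by systematic name, used for gene names only; the other 491 kept the name in the table. Each array was centred on its median. The test used the 6220 features with a value on all 8 time course arrays and left out 48. As each condition has 1 array, the number of arrays limits the precision, and the depth of an array has no further measure here.

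Changes were fitted with limma 3.58.1 in R 4.3.3, with a mean for each kinase at 0 min and at the later times. The times 15, 30 and 60 min served as repeated looks at the inhibited state. The p-value of a gene thus measures the spread between times, possibly of a single culture, and not between independent cultures. The fit has 4 residual degrees of freedom, and the lone 0 min array of each series is assumed to vary like the other arrays. Contrasts were later times minus 0 min for each kinase, their mean and their difference, with Benjamini-Hochberg adjustment over 6220 genes and a threshold of 0.05. Beside it stands the comparison the study itself names, AS against WT at the same time, fitted as the mean later ratio against 0 without subtraction of 0 min; it keeps differences between the strains and dyes that precede the inhibitor.

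A set of 34 gene lists with 835 members was written from general knowledge of yeast pathways. It was tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. No list passed with the estimate for the change on either kinase alone. Among lists that passed at the preset, the estimate lay below it for ribosome biogenesis (0.00184), general stress (0.00292), methionine and sulfur (−0.00322), TORC2-Ypk (−0.00953) and calcineurin genes (−0.0421). For these lists a larger correlation cannot account for the higher adjusted p, and the cause was not tested. For the other lists that passed, the estimate lay above the preset, up to 0.435 for core histones. Lists share members, and a list and a few genes are not reported. On single arrays, the median of a list was placed among 10000 random lists of the same size. The design, the lists, the threshold and most alternatives were chosen before the data were examined.

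Genes were named by a rule. YPK1 and YPK2 were always given. For each kinase, the rule took the 8 largest rises and 8 largest falls with an adjusted p under 0.05 and the same sign at all 3 later times, and for the mean and the difference of the kinases the 5 largest each way. Where fewer passed, the list was filled with the genes whose smallest change over the times was largest, and these are said not to pass. From each 0 min array and the WT array it took the 8 highest and 8 lowest ratios, and from each list spoken of up to 4 members with the largest change.

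The fit was tested on simulated values for 6220 genes, of which 200 were given a change in the Ypk1 series, in 5 runs. The noise was drawn independently with variances from the fit, so the outlying features of the real 0 min arrays play no part. Every gene without a given change had a true Ypk1 ratio of 0 at all times. Differences of strain or dye that precede the inhibitor are thus absent, and the false calls of the ratio test do not count them. The change against 0 min recovered 2.4%, 43.6%, 90.4% and 99.6% of changes of 1, 2, 3 and 4 on the log2 scale, with 8.4 false calls on average, and the ratio test recovered 51.6%, 99.6%, 99.6% and 100%, with 10 false calls. Camera recovered 20 of 20 shifted lists of 40 genes with 0 false calls. The simulated genes varied independently, so this cannot show the rate of false calls where genes of a list vary together. In the data the estimated correlation was 0.251 for ribosomal protein genes and 0.435 for core histones.

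Alternatives were no subtraction of 0 min, leaving out each later time, no centring, arrays scaled to a common median absolute deviation, quantile normalization, incomplete features kept, robust moderation, array weights, a linear trend over time, time as a factor, an adjusted p under 0.10, an added minimum log2 change of 1, fold thresholds of 1.5 and 3, and the estimated correlation. Added after the data were seen were the mean of both 0 min arrays as a common baseline, and the same settings applied to the ratio test and to the list medians. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.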

Results

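Transcript levels were measured in budding yeast that depend on a single member of a pair of related protein kinases, Ypk1 and Ypk2. Both chromosomal genes were deleted, and a plasmid supplied either the wild-type kinase (WT) or an analog-sensitive form (AS), a mutant whose ATP pocket accepts a bulky inhibitor that WT kinases exclude. On 8 arrays, RNA from AS cells was compared with RNA from WT cells given the same inhibitor for the same time, which asks which transcripts depend on the activity of each kinase. The Ypk1 series used 2,3-DMB-PP1 and the Ypk2 series 3-MB-PP1, each with 1 array at 0, 15, 30 and 60 min. The remaining array compared WT Ypk2 cells with WT Ypk1 cells without inhibitor, which asks whether the kinases are interchangeable at the level of transcripts. There was 1 array per condition, with no replicate arrays and no dye swaps, and this number limits the precision of every value. Values are log2 ratios, relative to the median gene of each array. A total of 6220 genes were measured on all 8 arrays of the time courses. In the Ypk1 series, 375 genes were at least 2-fold apart at 0 min, then 1560, 1184 and 1335 at 15, 30 and 60 min. In the Ypk2 series, the counts were 303 at 0 min, then 824, 756 and 1039. Below, a change is the mean of 15, 30 and 60 min minus 0 min, with its standard error from the fit (SE), and a ratio is the mean of the same times with its standard deviation over them (SD, n = 3).

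On the array of the WT strains, the genes of the kinases themselves followed the plasmids. There YPK2 (YMR104C) had the highest ratio of all genes, 5.49, and YPK1 (YKL126W) had −4.33. Within the Ypk1 series, YPK1 was higher in AS than in WT cells at all times, at 0.73, 0.82, 2.44 and 1.55, with a ratio of 1.60 ± 0.81 (SD, n = 3; adjusted p = 0.00955). Within the Ypk2 series, YPK2 was higher in AS cells at 1.06, 1.36, 1.53 and 1.36, with a ratio of 1.42 ± 0.09 (SD, n = 3; adjusted p = 0.00733). The deleted genes gave ratios too. YPK1 in the Ypk2 series ranged from −0.62 to 0.20. YPK2 in the Ypk1 series ran from 0.25 to 1.42 (ratio 0.96, adjusted p = 0.0173). YPK2 passed although both strains of that series lack the gene, so a passing ratio need not reflect a transcript of the named gene.

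At 0 min, the ratio of AS over WT cells was already high for ribosomal protein and core histone transcripts in both series. The median of 132 cytosolic ribosomal protein genes was 0.63 in the Ypk1 series and 0.56 in the Ypk2 series, and the 8 core histone genes, which package DNA, had medians of 0.86 and 0.80. Among 10000 random lists of the same size, the ribosomal protein medians lay at the 100 percentile and the histone medians at 99.99 and 99.95. Such percentiles treat genes as independent, while the estimated correlation was 0.251 for ribosomal protein genes and 0.435 for core histones. The 28 cell wall integrity genes were higher at 0 min as well, with medians of 0.35 and 0.29 at the 99.96 and 99.75 percentiles. Each 0 min value rests on 1 array, with AS cells always in the Cy5 channel. It has no error and cannot separate a strain difference from a dye effect. On the WT array, without AS cells, ribosomal protein genes (median 0.11, percentile 99.36) and cell wall integrity genes (0.50) also stood high. Core histones did not stand high there (−0.22, percentile 11.98). PHO84, the high-affinity phosphate transporter, was low in both series at 0 min, at −1.26 and −1.29, and stood at −0.78 on the WT array. The highest ratios of the Ypk1 0 min array belonged to YHL008C (4.85), PRX1 (4.74), a mitochondrial peroxiredoxin, YRF1-3 (4.66), a subtelomeric helicase gene, SHU1 (4.40), HKR1 (4.13), YER138C (3.83), HSE1 (3.38) and HSU1 (3.05). The lowest were YAL058C-A (−2.58), JEM1 (−2.56), PCH2 (−2.53), FYV5 (−2.44), ECM1 (−2.34), PHM6 (−2.22), BDH2 (−2.19) and the G1 cyclin CLN3 (−2.17). On the Ypk2 0 min array, TOF2 (3.39), AUS1 (3.36), the B-type cyclin CLB4 (3.33), YMR031W-A (3.01), DLT1 (2.73), SWD1 (2.62), TES1 (2.57) and SEN34 (2.47) were highest. MRX16 (−1.69), PHO84, TCM62 (−1.18), YML131W (−1.08), SUV3 (−1.05), MRD1 (−1.02), PRT1 (−0.98) and NOP7 (−0.97) were lowest. Of the 8 genes with an absolute ratio of 3 or more on the Ypk1 0 min array, 0 kept 50% of it after inhibitor. Across genes, the 0 min arrays of the series correlated with each other at r = 0.167.

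After 2,3-DMB-PP1, cells with AS Ypk1 held more transcript of cell wall integrity and general stress genes than WT cells and less of ribosome biogenesis genes. For the ratio, these lists had adjusted p of 0.000691, 3.46e-06 and 3.79e-09, and adjusted p of 0.325, 0.0743 and 0.0572 with an estimated correlation. YPS1 (YLR120C), a cell surface aspartyl protease, had a ratio of 2.86 ± 0.33 (SD, n = 3; adjusted p = 0.00107). YPT53, an endosomal Rab GTPase, stood at 3.46 ± 0.66 (adjusted p = 0.00107), RCN1, a regulator of the phosphatase calcineurin, at 2.17 ± 0.30 (adjusted p = 0.00175), and QDR2, a multidrug transporter, at 2.42 ± 0.33 (adjusted p = 0.00129). Lower in AS cells were PHO84 at −2.86 ± 0.25 (adjusted p = 0.000833), the ammonium transporter MEP2 at −2.51 ± 0.47 (adjusted p = 0.00129), YHR125W at −2.49 ± 0.12 (adjusted p = 0.000833) and MMP1, which imports S-methylmethionine, at −1.96 ± 0.27 (adjusted p = 0.00175). At 0 min YPS1 stood at 0.44, YPT53 at 0.63 and PHO84 at −1.26. By this test of the ratio against 0, a total of 1335 of 6220 genes passed, 681 higher and 654 lower in AS cells. Of these, 918 had the same sign at 0 min and 255 had at least 50% of the ratio there already. At every later time, 1115 lay further in the direction of the ratio than at 0 min, some of them after starting on the other side of 0. The count was 257 without 30 min and 313 without 60 min. Without centring 22.5% of 1549 calls were higher rather than 51.0%, since the median of all genes then lay at −0.29.

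When the single 0 min array was subtracted from the Ypk1 ratios, 3 genes passed, all with a fall: YHL008C by −5.21 ± 0.43 (SE), SHU1, a DNA repair gene, by −4.97 ± 0.41, and YRF1-3 by −4.92 ± 0.40, each with an adjusted p of 0.00207. Their ratios were above 4 at 0 min, and their later ratios did not pass the test against 0, with adjusted p of 0.250, 0.0779 and 0.371. The falls with the next largest minimum change over the later times did not pass: HKR1 (−4.74 ± 0.70), PRX1 (−3.67 ± 0.53), MMP1 (−2.84 ± 0.43), YHR125W (−2.57 ± 0.38) and YIL082W-A (−2.74 ± 0.54), with adjusted p from 0.0971 to 0.180. Among rises, 0 genes passed, though 21 of 59 calls were rises with scaled arrays, 21 of 48 with the mean of both 0 min arrays as the baseline and 31 of 88 with array weights. Those with the largest minimum change were YAL058C-A (3.76 ± 0.82), YAL035C-A (4.13 ± 0.96), BDH2 (3.84 ± 0.76), CLN3 (2.49 ± 0.51), PCH2 (3.90 ± 1.52), ECM1 (2.40 ± 0.53), QDR2 (2.46 ± 0.48) and YDR215C (2.59 ± 0.46). Of these, YAL058C-A, BDH2, CLN3, PCH2 and ECM1 were among the 8 lowest genes of the Ypk1 0 min array. The later ratios of CLN3 (0.32, adjusted p = 0.396), ECM1 (0.06, adjusted p = 0.896), YAL058C-A (1.18, adjusted p = 0.0716) and PCH2 (1.37, adjusted p = 0.229) did not pass. An unadjusted p under 0.05 was reached by 703 genes. Leaving out 30 min or 60 min reduced the count from 3 to 0.

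Ribosome biogenesis transcripts, which encode factors that build ribosomes, fell on Ypk1 inhibition with a median change of −1.15 over 48 genes (adjusted p = 2.36e-08; adjusted p = 0.0678 with an estimated correlation). By the ratio, 31 of them were lower in AS cells, 3 were higher and 14 did not pass. The numbers adjusted over the list alone were 33 lower and 6 higher. NOP56, a nucleolar protein, had a change of −2.47 ± 0.69 (SE), UTP10 −2.32 ± 0.52, ARX1 −2.14 ± 0.43 and RLP7 −1.90 ± 0.68. None of these changes passed over all genes. The ratio of UTP10 did, at −2.09 ± 0.11 (SD, n = 3; adjusted p = 0.00207). General stress genes under the activators Msn2 and Msn4 rose by a median of 0.82 over 40 genes (adjusted p = 3.86e-05; adjusted p = 0.105 with an estimated correlation). Of these, 19 were higher by the ratio, 0 were lower and 21 did not pass, with 22 higher adjusted over the list alone. MSC1 had a change of 2.32 ± 0.64, TFS1, an inhibitor of carboxypeptidase Y, 1.92 ± 0.84, the glycogen synthase gene GSY1 1.72 ± 1.67 and DCS2 1.63 ± 0.55.

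Methionine and sulfur genes fell on Ypk1 inhibition, with a median change of −0.43 over 23 genes (adjusted p = 0.00329; adjusted p = 0.195 with an estimated correlation). By the ratio 6 were lower, 2 higher and 15 did not pass, against 9 lower and 2 higher adjusted over the list alone. Besides MMP1, MET1 had a change of −2.42 ± 0.47 (SE), the S-adenosylmethionine transporter gene SAM3 −1.98 ± 0.42 and MET8 −1.51 ± 0.44. Osmotic stress genes under the kinase Hog1 rose by a median of 0.82 over 17 genes (adjusted p = 0.0131; adjusted p = 0.465 with an estimated correlation). By the ratio 8 were higher, 2 lower and 7 did not pass, and adjusted over the list alone the numbers were again 8 and 2. GPD1, which makes glycerol, had a change of 2.12 ± 0.43, the sodium pump ENA1 1.59 ± 0.40, GCY1 1.46 ± 0.48 and HOR7 1.41 ± 0.62. The osmotic call was lost without 60 min (0.64, adjusted p = 0.0568) and with arrays scaled to one spread (0.54, adjusted p = 0.0887).

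Genes of the TORC2-Ypk pathway itself, 22 in number with YPK1 and YPK2 among them, rose on Ypk1 inhibition by a median of 0.36 relative to all genes (adjusted p = 0.0208; adjusted p = 0.295 with an estimated correlation), though without centring the median was −0.16 and that of all genes −0.51. Of them, 5 were higher by the ratio, 0 lower and 17 did not pass, with 5 higher adjusted over the list alone. The 5 include YPK1, supplied by the plasmid that differs between the strains, and YPK2, which both strains lack. ORM2, a regulator of sphingolipid synthesis, had a change of 1.20 ± 0.55 (SE), TSC11 1.10 ± 0.47 and PKH2 0.91 ± 0.39. The call was lost without 60 min (0.31, adjusted p = 0.0568), with scaled arrays (0.27, adjusted p = 0.106) and with quantile normalization (0.35, adjusted p = 0.0792).

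Ribosomal protein genes fell on Ypk1 inhibition by a median change of −0.43 over 132 genes (adjusted p = 0.00151; adjusted p = 0.596 with an estimated correlation). Only 47 lay below 0 min at every later time and 11 lay above, and the median at 15 min, 0.68, was not below that at 0 min, 0.63. By the ratio 11 were higher, 11 lower and 110 did not pass, with 11 and 10 adjusted over the list alone. The changes of RPL27B (−2.06 ± 0.62, SE), RPL3 (−1.94 ± 0.68), RPL12B (−1.82 ± 0.65) and RPS27A (−1.75 ± 0.45) were the largest. The call was lost without 30 min (−0.30, adjusted p = 0.0672) and without 60 min (−0.27, adjusted p = 0.0568), and without subtraction of 0 min the median was 0.15 (adjusted p = 0.433). The 8 core histone genes fell by a median of −0.93 (adjusted p = 0.0182; adjusted p = 0.471 with an estimated correlation), with HHT1 at −1.34 ± 0.57, HHT2 at −1.30 ± 0.72 and HHF1 at −1.10 ± 0.61. By the ratio 1 was higher, 0 were lower and 7 did not pass, with 1 higher adjusted over the list alone. The histone call was lost without 60 min (−0.66, adjusted p = 0.0828) and without subtraction (−0.19, adjusted p = 0.973).

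Cell wall integrity genes, the targets of the Slt2 pathway that maintains the wall, missed the threshold for the change on Ypk1 inhibition (median 0.34 over 28 genes, adjusted p = 0.0566; adjusted p = 0.495 with an estimated correlation). By the ratio 11 were higher in AS cells, 1 was lower and 16 did not pass, with 12 and 1 adjusted over the list alone. NCW2, a cell wall protein, had a ratio of 3.41 ± 1.17 (SD, n = 3; adjusted p = 0.00207) and SLT2, the kinase of the pathway, had 1.19 ± 0.47. Of the 34 lists, 7 passed for the Ypk1 change.

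**Figure D1:**
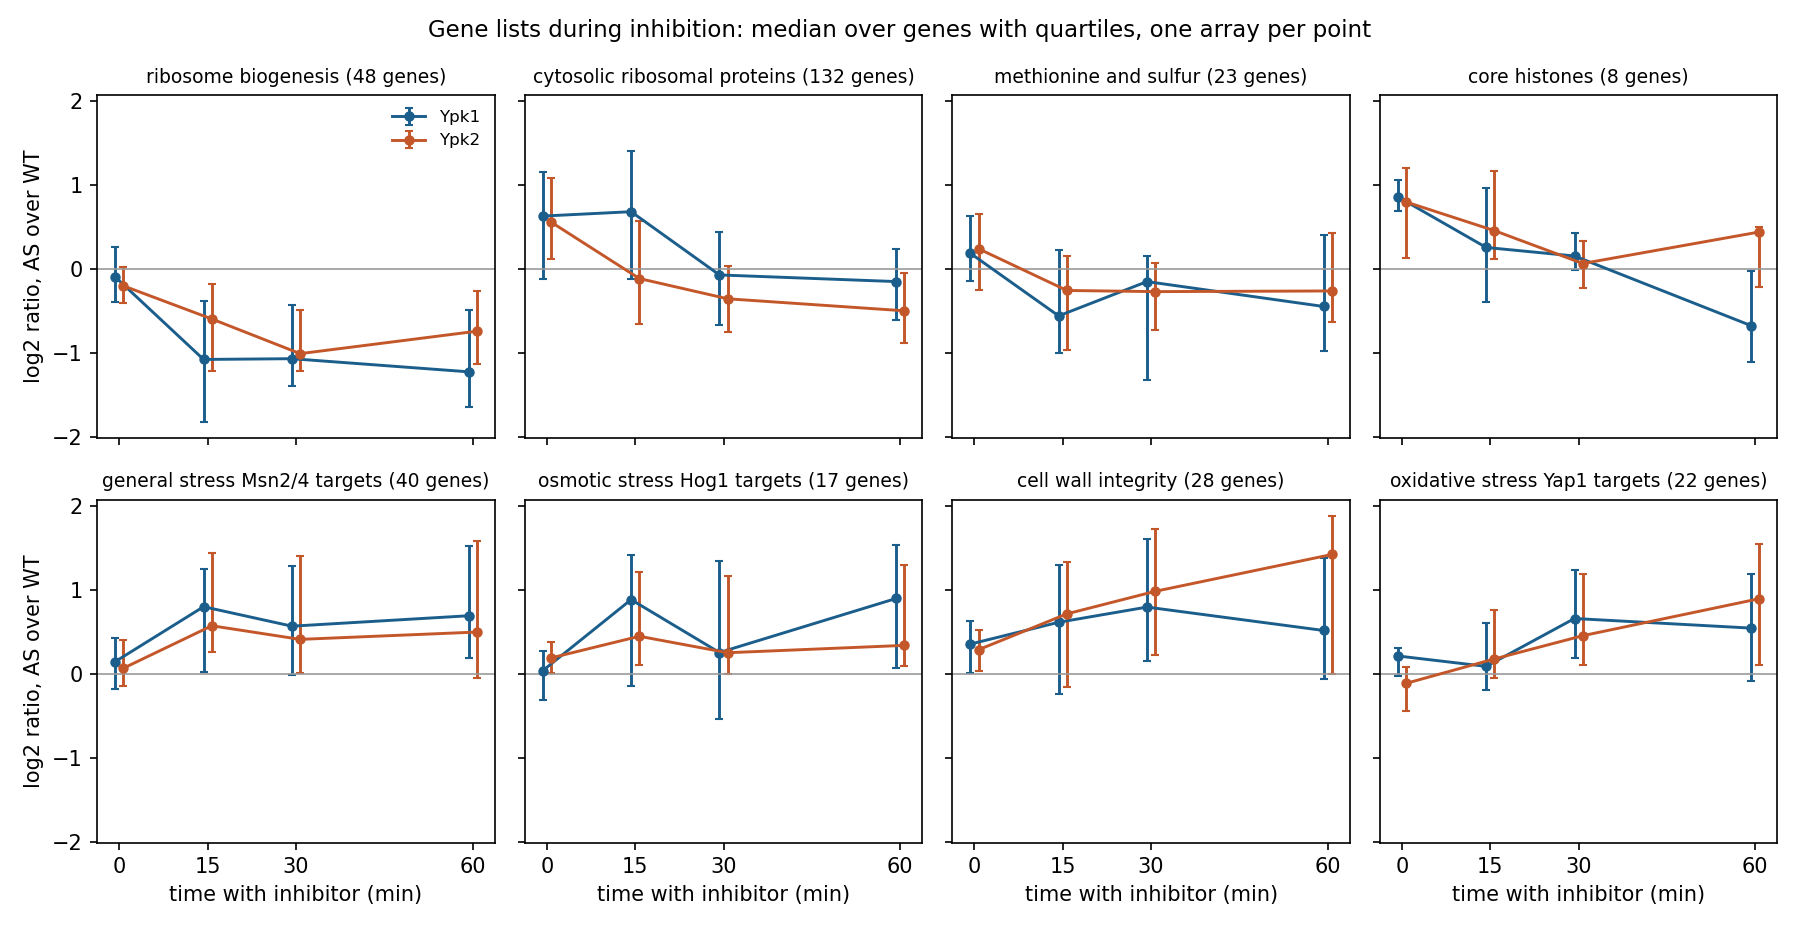
Median log2 ratio of AS over WT cells (y axis) against time with inhibitor in min (x axis) for 8 gene lists, with bars from the lower to the upper quartile of the genes, Ypk1 in blue and Ypk2 in orange. Ribosome biogenesis falls from −0.10 and −0.20 at 0 min to between −1.22 and −0.60 at later times, while general stress genes move from 0.15 and 0.07 to between 0.41 and 0.80; without centring each point shifts by its array's median, which ranges from −0.52 to 0.23.

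After 3-MB-PP1, cells with AS Ypk2 likewise held more transcript of cell wall integrity and general stress genes than WT cells and less of ribosome biogenesis genes. For the ratio, the adjusted p of these lists was 3.96e-06, 3.96e-06 and 3.09e-11, and the adjusted p with an estimated correlation was 0.323, 0.0798 and 0.0388. HSP12, a membrane-associated stress protein, had a ratio of 2.81 ± 0.20 (SD, n = 3; adjusted p = 0.00172). YPS1 stood at 2.76 ± 0.60 (adjusted p = 0.00191), RCN1 at 2.49 ± 0.47 (adjusted p = 0.00191), QDR2 at 2.62 ± 0.48 (adjusted p = 0.00191) and YPT53 at 2.97 ± 0.51 (adjusted p = 0.00191). PHO3, an acid phosphatase, was lower at −2.53 ± 0.15 (adjusted p = 0.00172), PHO84 at −2.10 ± 0.31 (adjusted p = 0.00194) and MEP2 at −1.67 ± 0.38 (adjusted p = 0.00637). At 0 min YPS1 already stood at 1.13, YPT53 at 0.80, HSP12 at 0.67 and PHO84 at −1.29. By the ratio, 728 of 6220 genes passed, 434 higher and 294 lower in AS cells. Of these, 613 had the same sign at 0 min and 233 had at least 50% of the ratio there. The count was 0 without 30 min and 0 without 60 min, 1214 with scaled arrays, 1481 with quantile normalization and 4157 with array weights. Without centring 26.9% of 840 calls were higher rather than 59.6%, since the median of all genes then lay at −0.28.

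With 0 min subtracted, limma called 0 genes on Ypk2 inhibition, with a smallest adjusted p of 0.163, and 321 genes had an unadjusted p under 0.05. Chosen for the largest minimum change over the later times, the rises were YMR084W (2.40), ALD4 (2.38), a mitochondrial aldehyde dehydrogenase gene, CPP3 (2.35), RCN1 (2.27 ± 0.47, SE), RCN2 (2.23), another calcineurin regulator, YNL208W (2.19), HSP12 (2.13 ± 0.44) and the trehalose synthesis gene TPS1 (2.01). Falls chosen the same way were TOF2 (−3.73), CLB4 (−3.36), SWD1 (−3.05), YAR061W (−2.61), DLT1 (−2.57), YOR309C (−2.37), PRY1 (−2.36) and YLR296W (−2.25). TOF2, CLB4, SWD1 and DLT1 were among the highest genes of the Ypk2 0 min array, and without subtraction DLT1 stood at 0.16.

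Ribosomal protein genes fell on Ypk2 inhibition, with a median change of −0.90 over 132 genes and 99 of them below 0 min at every later time (adjusted p = 3.69e-20; adjusted p = 0.335 with an estimated correlation). By the ratio 13 were lower, 1 was higher and 118 did not pass, as also when adjusted over the list alone. Without subtraction of 0 min, where the median was 0.56, the median was −0.29 (camera adjusted p = 0.000480, or 0.542 with an estimated correlation). RPS16B (−2.52 ± 0.78, SE), RPL31B (−2.46 ± 0.80), RPS10A (−2.25 ± 0.83) and RPS30B (−2.21 ± 0.79) had the largest changes. Many of these genes have a near-identical copy, and an array spot can bind both. Ribosome biogenesis genes fell by a median of −0.47 over 48 genes (adjusted p = 3.53e-07; adjusted p = 0.0590 with an estimated correlation). By the ratio 18 were lower, 0 higher and 30 did not pass, against 28 lower and 1 higher adjusted over the list alone. BRX1 had a change of −2.23 ± 0.55, the RNA polymerase I subunit genes RPA135 and RPA190 had −1.83 ± 0.38 and −1.76 ± 0.46, and RRP12 had −1.57 ± 0.40. Methionine and sulfur genes fell by a median of −0.19 over 23 genes (adjusted p = 0.00325; adjusted p = 0.216 with an estimated correlation). By the ratio 5 were lower, 1 higher and 17 did not pass, against 5 lower and 2 higher adjusted over the list alone. MET2 (−1.65 ± 0.59), the sulfate transporter gene SUL2 (−1.61 ± 0.56), SAM1 (−1.60 ± 0.50) and SAM3 (−1.56 ± 0.42) had the largest changes. Without subtraction of 0 min the call was lost (−0.28, adjusted p = 0.0753).

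General stress genes rose on Ypk2 inhibition by a median of 0.53 over 40 genes (adjusted p = 3.53e-07; adjusted p = 0.0590 with an estimated correlation). Of these, 16 were higher by the ratio, 0 lower and 24 did not pass, against 18 higher and 2 lower adjusted over the list alone. TFS1 had a change of 2.58 ± 0.84 (SE), and ALD3, an aldehyde dehydrogenase gene, had 1.91 ± 0.59. Oxidative stress genes under the activator Yap1 rose by a median of 0.54 over 22 genes (adjusted p = 1.33e-05; adjusted p = 0.335 with an estimated correlation). By the ratio 7 were higher, 1 lower and 14 did not pass, against 8 and 1 adjusted over the list alone. The peroxiredoxin gene TSA1 had a change of 1.71 ± 0.63, AAD14 1.48 ± 0.65, PRX1 1.30 ± 0.53 and GPX2 1.24 ± 0.55. With the mean of both 0 min arrays as the baseline, PRX1 stood at −1.38. On Ypk1 inhibition the change of the oxidative stress list did not pass (median 0.35, camera adjusted p = 0.3463). Its Ypk1 ratio did pass (camera adjusted p = 0.0181, or 0.42 with an estimated correlation).

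Cell wall integrity genes rose on Ypk2 inhibition by a median of 0.37 over 28 genes (adjusted p = 0.000204; adjusted p = 0.335 with an estimated correlation). By the ratio 13 were higher, 0 lower and 15 did not pass, against 17 and 1 adjusted over the list alone. NCW2 had a change of 2.41 ± 0.86 (SE), the chitin synthase gene CHS1 1.87 ± 0.47 and YPS1 1.63 ± 0.52. Calcineurin targets under the activator Crz1 share GSC2, CRH1, NCW2 and YPS1 with the wall genes. They rose by a median of 0.39 over 16 genes (adjusted p = 0.00581, or 0.216 with an estimated correlation). Of these, 7 were higher by the ratio, 0 lower and 9 did not pass, the same numbers as adjusted over the list alone. GYP7 had a change of 1.70 ± 0.51. The median ratio of the calcineurin list was 0.04. On Ypk1 inhibition its change did not pass (median −0.06, camera adjusted p = 0.1845). With scaled arrays the wall call was lost (0.48, adjusted p = 0.0549), as was the calcineurin call (0.39, adjusted p = 0.0653). With quantile normalization both had an adjusted p of 0.0832. The calcineurin call was also lost with the mean of both 0 min arrays as the baseline (0.04, adjusted p = 0.0662).

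Proteasome and osmotic stress genes passed more narrowly on Ypk2 inhibition. Proteasome genes rose by a median of 0.28 over 32 genes (adjusted p = 0.0387; adjusted p = 0.509 with an estimated correlation). By the ratio 4 were higher, 1 lower and 27 did not pass, against 7 and 1 adjusted over the list alone. PRE2 had a change of 1.07 ± 0.39 (SE), PRE10 0.98 ± 0.57, PRE8 0.87 ± 0.39 and PRE1 0.78 ± 0.57. Osmotic stress genes rose by a median of 0.28 over 17 genes (adjusted p = 0.0463; adjusted p = 0.509 with an estimated correlation). By the ratio 6 were higher, 0 lower and 11 did not pass, against 7 higher adjusted over the list alone. GRE2 had a change of 1.13 ± 0.58, SIP18 1.04 ± 0.49, DAK1 −0.96 ± 0.99 and GPP2 0.95 ± 0.39. Both calls were lost with scaled arrays (adjusted p of 0.170 for the proteasome and 0.275 for osmotic stress), with quantile normalization (0.192 and 0.348), without 30 min (0.0585 and 0.0653) and without 60 min (both 0.0667). The osmotic call was also lost without 15 min (0.102).

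**Figure D2:**
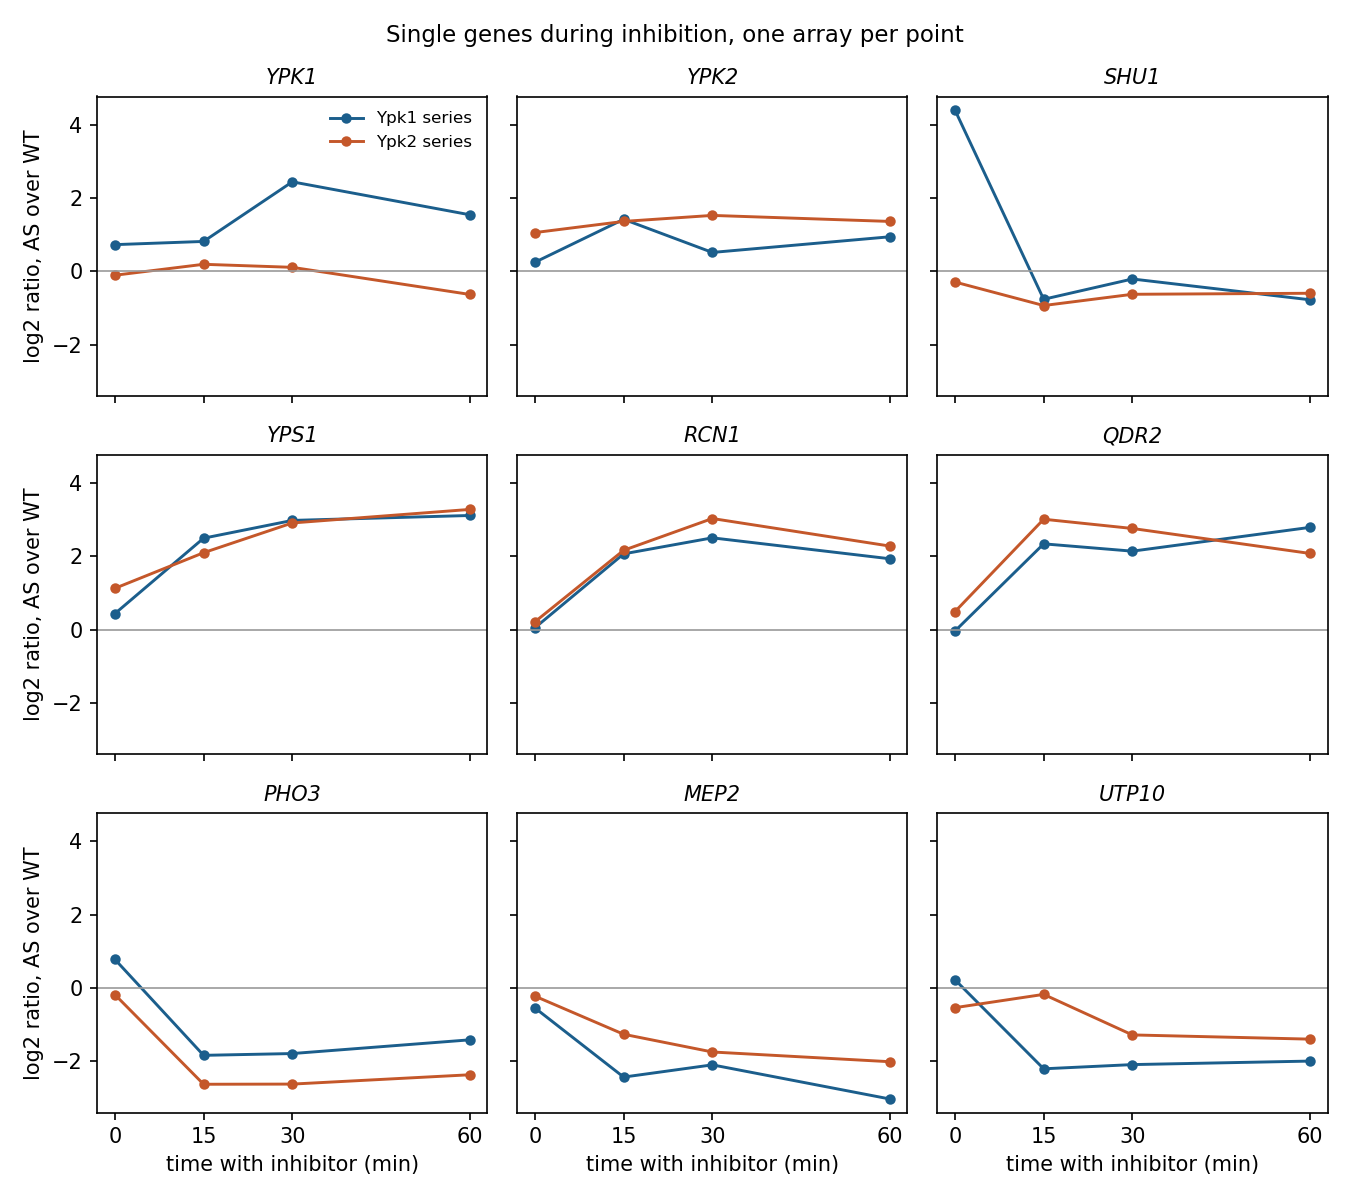
Log2 ratio of AS over WT cells (y axis) against time with inhibitor in min (x axis) for 9 named genes, 1 array per point, Ypk1 in blue and Ypk2 in orange. YPS1, RCN1 and QDR2 lie above 1 at every later time in both series and PHO3 below −1, while SHU1 is at 4.40 on the Ypk1 0 min array alone.

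Averaged over both kinases, PHO3 fell with a change of −2.40 ± 0.28 (SE; adjusted p = 0.0267) and lay below its 0 min value at every later time in both series. Ratios of PHO3 were −1.68 ± 0.23 (SD, n = 3) for Ypk1 and −2.53 ± 0.15 for Ypk2, and its sequence is similar enough to that of PHO5 that a spot can bind both. SHU1 (−2.70), YHL008C (−2.66) and YRF1-3 (−2.41) also passed with an adjusted p of 0.0267, and these are 3 of the genes above 4 on the Ypk1 0 min array. The remaining genes with the largest minimum change over the times did not pass: YPT53 (2.50 ± 0.41), ALD4 (2.43 ± 0.42), QDR2 (2.29 ± 0.34), RCN1 (2.19 ± 0.33) and YOR385W (2.14 ± 0.32) above 0, and the mating pheromone gene MF(ALPHA)1 (−1.94 ± 0.32) and SAM3 (−1.77 ± 0.30) below. Their adjusted p was 0.0778 or, for ALD4, 0.0856. An unadjusted p under 0.05 was reached by 826 genes. The count of 4 was 15 without 15 min and 0 without 30 min, without 60 min, with time as a factor in the fit or with the mean of both 0 min arrays as the baseline, so the call of PHO3 was lost in these. Of the 34 lists, 5 passed for each kinase taken alone, and averaged over both kinases ribosome biogenesis (adjusted p = 0.0474) and general stress (adjusted p = 0.0474) held with an estimated correlation.

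The ratios after inhibitor overlapped between the series. By the ratio test, 322 genes were higher in AS cells of both series and 193 were lower in both. In opposite directions there was 1 gene, SSM4, picked out after its values were seen, at 0.79 for Ypk1 and −0.89 for Ypk2. This overlap can include differences of strain and dye that precede the inhibitor, which the ratio keeps, but their part in it was not measured. Of all calls, shared or not, 918 of 1335 for Ypk1 and 613 of 728 for Ypk2 had the same sign at 0 min. The Ypk2 calls number 0 without 30 min or without 60 min. At least 2-fold apart at all 3 later times were 174 genes higher and 155 lower for Ypk1, and 184 higher and 58 lower for Ypk2. Shared by both were 81 higher and 32 lower genes. Without centring the share of higher genes dropped from 52.9% to 21.9% for Ypk1 and from 76.0% to 32.2% for Ypk2. Across the 6220 genes, which are not independent replicates, the changes correlated at r = 0.407 (Spearman 0.368), although they share no array, and the ratios at r = 0.693 (Spearman 0.644). With arrays scaled to one spread the r of the changes was 0.225, and with quantile normalization 0.222.

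**Figure D3:**
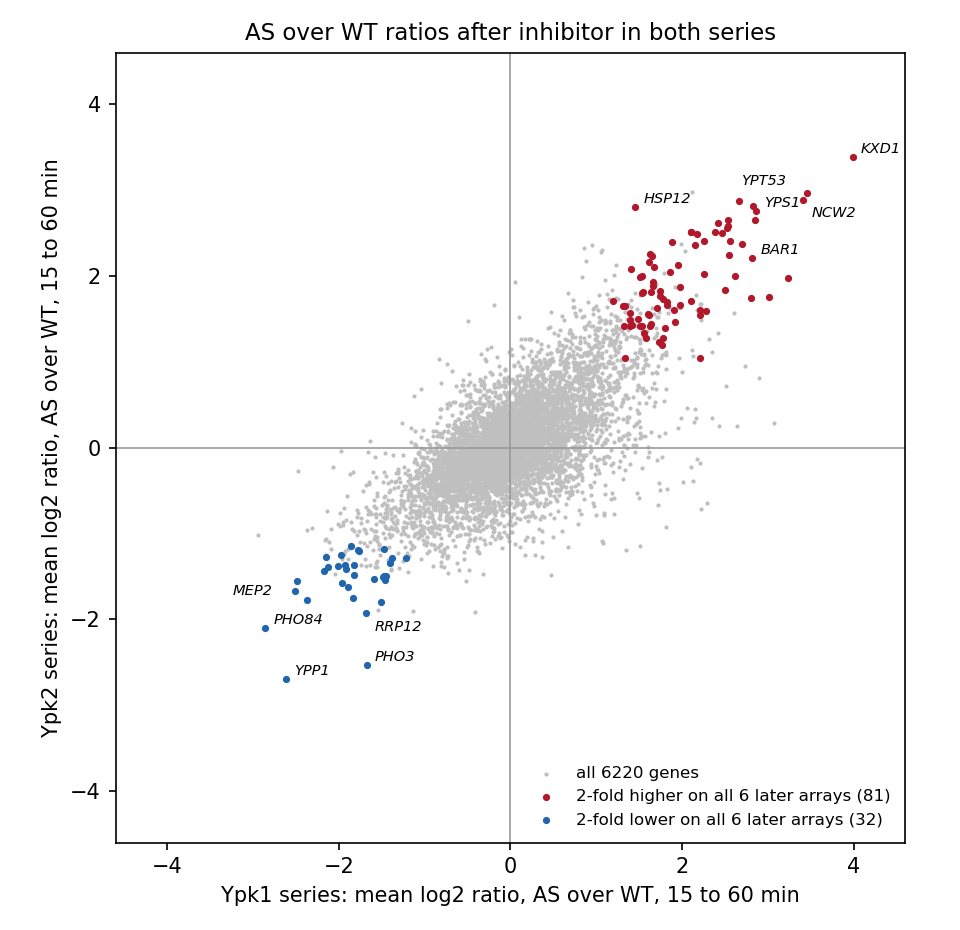
Mean log2 ratio of AS over WT cells at 15, 30 and 60 min for Ypk1 (x axis) against Ypk2 (y axis), with 6220 genes in grey. The 81 genes at least 2-fold higher on all 6 later arrays are in red and the 32 at least 2-fold lower in blue; across all genes r = 0.693.

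The inhibitors, PP1 analogs that differ by a methyl group on the benzyl ring, were used at different doses, 0.5 µM for 2,3-DMB-PP1 and 1 µM for 3-MB-PP1, and each on another kinase, so kinase, compound and dose cannot be told apart. Side by side, YPS1 had ratios of 2.86 and 2.76 and a difference of changes, Ypk1 minus Ypk2, of 0.79 (95% interval −0.89 to 2.47). For RCN1 the difference was −0.16 (−1.68 to 1.36), for NCW2 −0.13 (−2.89 to 2.63), for PHO3 −0.10 (−1.36 to 1.15), for MEP2 −0.52 (−2.10 to 1.05) and for PHO84 −0.80 (−2.15 to 0.56). HSP12 had ratios of 1.45 ± 0.40 (SD, n = 3) and 2.81 ± 0.20, and the difference of its changes was −1.23 (−2.63 to 0.17). Ribosomal protein genes were the single list whose changes differed, by a median of 0.45 (adjusted p = 0.00428; adjusted p = 0.834 with an estimated correlation). Their medians ran 0.63, 0.68, −0.07 and −0.15 over the Ypk1 times and 0.56, −0.11, −0.36 and −0.50 over the Ypk2 times. The call was lost without 15 min (0.29, adjusted p = 0.0923) and with quantile normalization (0.41, adjusted p = 0.0575). Without centring the median of the difference was −0.012 and that of all genes −0.48.

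By limma 0 genes passed for the difference of the changes, with a smallest adjusted p of 0.0525, and 168 had an unadjusted p under 0.05. By the ratios 0 genes passed as well (smallest adjusted p 0.269), with 602 at an unadjusted p under 0.05. The positive differences with the largest minimum over the times were YAL035C-A (4.56 ± 1.36, SE), YAL058C-A (4.47 ± 1.16), DDI3 (3.81 ± 1.80), BDH2 (3.06 ± 1.08) and TOF2 (3.06 ± 0.66). The negative ones chosen the same way were YHL008C (−5.10 ± 0.60), YRF1-3 (−5.02 ± 0.57), PRX1 (−4.96 ± 0.75), SHU1 (−4.55 ± 0.59) and HKR1 (−4.36 ± 0.99). The 95% interval of a gene's difference had a median half-width of 1.58, and for 0 of the 6220 genes did it lie within 1 of 0, so the arrays do not show that the responses were alike for any gene.

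Without inhibitor, WT Ypk2 cells held more transcript of respiratory, general stress and cell wall integrity genes than WT Ypk1 cells. The 35 oxidative phosphorylation genes had a median of 0.62, above all 10000 random lists of that size, with SDH2 at 1.53, ATP16 at 1.51, NDI1 at 1.36 and COX7 at 1.16. Retrograde genes, which respond to mitochondrial state, had a median of 0.62, cell wall integrity genes 0.50 (SPI1 1.33) and general stress genes 0.44 (HSP12 3.45, YGP1 2.14, TFS1 1.76, DDR2 1.61), each also above all random lists. The Ypk1 0 min array holds no Ypk2 cells, yet oxidative phosphorylation (0.25, percentile 99.76), retrograde (0.26, 96.38) and general stress genes (0.15, 96.51) stood high there too. On the Ypk2 0 min array these 3 lists were less set apart, at 0.11 (89.04), −0.02 (44.88) and 0.07 (80.44). Cell wall integrity genes stood high on both 0 min arrays. Phosphate genes had a median of −0.39 (percentile 0.35), with PHM6 at −2.29 and PHO86 at −1.33, but PHO5 at 0.82 and PHM8 at 0.79. Oxidative stress genes (0.08, percentile 76.7) and the unfolded protein response (−0.06, percentile 30.9) were not set apart. Besides YPK2 and HSP12, the highest genes were KXD1 (2.90), REC8 (2.57), RBG1, YNL194C, LEU2 and PUG1 (2.46 each). Besides YPK1 the lowest were RPL11A (−4.97), RSB1 (−3.03), SHP1 (−2.94), ORC5 (−2.92), YBL065W (−2.67), YIP4 (−2.50) and NPR1 (−2.37). In all, 319 genes were at least 2-fold apart, 172 higher with Ypk2 and 147 lower. Without centring the share of higher genes was 28.5% rather than 53.9%. A single array gives no error for these values, and it cannot separate a strain difference from a dye effect.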

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

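The tests on the genes far from 0 at 0 min and on the resemblance of the Ypk1 and Ypk2 changes were chosen only after the result was seen.

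The difference between the Ypk1 and Ypk2 changes passed its own test for the ribosomal protein genes, with a median of 0.45 (adjusted p = 0.00428; adjusted p = 0.834 with an estimated correlation). YAL035C-A moved up against 0 min at every later time for Ypk1 and down for Ypk2, a difference of 4.56 that did not pass (adjusted p = 0.998). DDI3 did likewise, with a difference of 3.81 (adjusted p = 0.998). PRX1 moved the opposite way in the series, down for Ypk1 and up for Ypk2, with a difference of −4.96 (adjusted p = 0.180).

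Several genes, among them YHL008C, SHU1, YRF1-3 and PRX1, had ratios of 3 or more on the Ypk1 0 min array alone, and they supply all 3 genes called for Ypk1. A lasting difference between the AS and WT strains is argued against for these 8 genes. The median share of the 0 min ratio that they kept after inhibitor was 0.0616, and 0 of 8 kept at least 0.5. Among the 8 lowest genes of that array, JEM1 (−2.56, then −2.68, −3.82 and −2.32) and PHM6 (−2.22, then −1.83, −1.80 and −1.59) did keep most of theirs, while the rest did not. Faults of neighbouring spots on that array are a candidate explanation: 13 of the 30 most extreme features lay within 10 positions of another in the table, against at most 6 in 95% of random draws, and on the Ypk2 0 min array the number was 12, against 2 to 5 on later arrays. The order of the table need not be the order of spots on the glass. Some of the 8 highest and 8 lowest genes of the Ypk1 0 min array also lie close together on a chromosome. BDH2, ECM1 and CLN3 lie on chromosome I, and YHL008C and SHU1 on chromosome VIII. The count therefore cannot tell neighbouring spots from neighbouring genes. No biological explanation was tested for this pattern.

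The changes on Ypk1 and on Ypk2 inhibition resembled each other. A dye or strain bias that is the same on every array would cancel when 0 min is subtracted, and the r of 0.407 across genes between changes that share no array argues against it as the whole cause. A shared function of the kinases and an effect common to PP1 analogs in AS cells both stay open, since kinase, compound and dose vary together and no array holds an AS strain with another kinase blocked by the same compound. The size of r depends on scaling, at 0.225 with arrays scaled to one spread.

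WT Ypk2 over WT Ypk1 ratios resembled the ratios after Ypk2 inhibition (r = 0.440 across genes, Spearman 0.408), but also the Ypk1 0 min array (r = 0.404, Spearman 0.484), so the resemblance is not particular to inhibition. A dye bias that is the same on every array is argued against as the whole cause by the r of 0.282 with the Ypk2 change, in which such a bias cancels. Less kinase function in cells with Ypk2 than in cells with Ypk1 predicts a resemblance to the Ypk1 change as well. That r was −0.00272 (Spearman −0.053). A value of 0 or below had been set beforehand as counting against this explanation, but the spread of r was not measured. The later Ypk1 ratios gave 0.290. These values point different ways, and the Ypk1 change subtracts the very 0 min array that resembles the WT array, so this explanation stays open, as does a difference between strains or cultures on a single array.

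Other splits of the 6 later arrays into groups of 3 decide nothing about the 0 genes that differ between the kinases, since each of the 10 splits gives at least 0 whatever the data; the highest other split gave 5. Other choices of the baseline array are too few to give a share under 0.05: 3 of 16 choices gave as many genes as the 4 called on average over both kinases. The highest other, with 15 min as the baseline of both series, gave 27, several times the real count, which points to a structure of the arrays whose nature was not tested.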

How the results depend on the processing

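The mean of both 0 min arrays as a common baseline, all settings of the ratio test, and the list medians under quantile normalization, were chosen only after the data were seen. For each result the cause of a shift was not tested unless a sentence says so. The Ypk1 change called 3 genes; no subtraction of 0 min gave 1335, leaving out a time 0 to 4, no centring 6, scaled arrays 59, quantile normalization 19, array weights 88, a linear trend 0, the common baseline 48 and an adjusted p under 0.10 7. The Ypk2 change called 0 by limma (321 at an unadjusted p under 0.05); no subtraction gave 728, scaled arrays 12, quantile normalization 12 and array weights 159. The average called 4; no subtraction gave 1937, leaving out a time 0 to 15, scaled arrays 81, quantile normalization 67, array weights 640, a linear trend 41, time as a factor 0, the common baseline 0 and an adjusted p under 0.10 34. The difference called 0; no centring gave 3, scaled arrays 12, quantile normalization 7, robust moderation 2, array weights 4 and an adjusted p under 0.10 3. With array weights the estimation did not converge to its tolerance.

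Of the ratio calls, 1335 for Ypk1 ranged from 257 to 1165 when a time was left out, and 728 for Ypk2 from 0 to 756; for Ypk2 scaled arrays gave 1214, quantile normalization 1481 and array weights 4157. Lists for Ypk1, 7 by the preset correlation, numbered 0 with the estimated correlation, 12 without subtraction, 3 to 10 without a time and 12 with the common baseline. Lists for Ypk2, 10 by the preset, numbered 0 with the estimated correlation, 5 with scaled arrays and 6 with a linear trend. The correlation of the changes was 0.693 without subtraction, 0.225 with scaled arrays and 0.222 with quantile normalization. Genes 2-fold apart at every later time were 143 for Ypk1 with scaled arrays, and at 1.5-fold and 3-fold they were 893 and 59 for Ypk1 and 779 and 56 for Ypk2. On the WT array the counts were 730 with scaled arrays, 1373 at 1.5-fold and 56 at 3-fold; a lower or higher fold threshold raises or lowers a count by construction.

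Direction turned in these cases. Without subtraction of 0 min, PRX1 for Ypk1 stood at 1.07, RPL12B at 0.41, HHF2 at 0.40, DLT1 for Ypk2 at 0.16 and the median of the ribosomal proteins for Ypk1 at 0.15, since their 0 min ratios were high. With the common baseline PRX1 for Ypk2 stood at −1.38, which the Ypk1 0 min array sets. Of the alternatives for single named genes, 941 kept direction and side of the threshold, 155 newly passed, 15 no longer passed and 5 turned; of those for called lists, 111 kept both, 30 no longer passed and 3 changed sign. Of these 3, 2 did so only without centring, where all genes shift alike, so neither list turned against other genes: the TORC2-Ypk pathway for Ypk1 (−0.16, all genes −0.51) and the ribosomal protein difference (−0.012, all genes −0.48). The alternative for genes with several probes was not run, as no gene has more than 1 feature, and incomplete features had no meaning for the single WT array. Without intensities, signal over background is unknown.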

Other observations

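The counts of the ratio test without 30 min or 60 min were chosen only after the result was seen, while the ratio test itself was planned.

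Beyond the lists that passed, several metabolic genes differed between AS and WT cells after inhibitor, by the ratio against 0 whose counts without 30 or 60 min fell from 1335 to 257 and 313 for Ypk1 and from 728 to 0 and 0 for Ypk2. The high-affinity iron uptake genes FET3 and FTR1 had ratios of −1.89 ± 1.07 (SD, n = 3; adjusted p = 0.00844) and −1.78 ± 0.74 (adjusted p = 0.00395) for Ypk1, and −1.62 ± 0.35 (adjusted p = 0.0239) and −1.19 ± 0.15 (adjusted p = 0.0270) for Ypk2. Meanwhile the 24 iron genes as a list did not pass for the change (adjusted p = 0.780 and 0.822; for Ypk1 the median was 0.08 and the mean −0.21). By the ratio 4 of them were higher and 5 lower for Ypk1, and 2 were higher and 4 lower for Ypk2, with the heme oxygenase gene HMX1 higher at 1.18 ± 0.56 (adjusted p = 0.0261) and 1.38 ± 0.69 (adjusted p = 0.0238). In the phosphate regulon, the acid phosphatase genes PHO5 and PHO11 stood at −2.36 ± 1.05 (adjusted p = 0.00362) and −2.07 ± 0.80 (adjusted p = 0.00337) for Ypk1, and the transporter gene PHO89 went the other way at 0.93 ± 0.27 (adjusted p = 0.0154). For Ypk2, PHO5 had −1.78 ± 0.34 (adjusted p = 0.0165), PHO11 −0.22 ± 0.35 (adjusted p = 0.681) and PHO89 0.89 ± 0.26 (adjusted p = 0.0284). The list of 16 did not pass for the change (adjusted p = 0.268 and 0.323), while by the ratio it passed for Ypk1 (adjusted p = 0.0181; adjusted p = 0.245 with an estimated correlation) with 7 lower and 1 higher. Of the nitrogen genes, DAL2, which degrades allantoate, had −1.82 ± 0.62 (adjusted p = 0.00395) for Ypk1 and −0.97 ± 0.48 (adjusted p = 0.0581) for Ypk2. The amino acid permease gene GAP1 had −1.29 ± 0.36 (adjusted p = 0.00444) and −1.40 ± 0.10 (adjusted p = 0.00638), while PUT1, which degrades proline, was higher at 1.52 ± 0.08 (adjusted p = 0.00336) and 1.42 ± 0.45 (adjusted p = 0.00733). Of the 22 nitrogen genes, 1 was higher and 6 lower by the ratio for Ypk1 and 2 were higher and 2 lower for Ypk2, and the list did not pass for the change (adjusted p = 0.0704 and 0.323).

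The peroxisomal citrate synthase gene CIT2, a target of the retrograde pathway, had ratios of 2.54 ± 0.89 (SD, n = 3; adjusted p = 0.00207) for Ypk1 and 2.65 ± 0.34 (adjusted p = 0.00344) for Ypk2. The drug efflux pump gene PDR5 had 1.86 ± 0.50 (adjusted p = 0.00208) and 2.05 ± 0.22 (adjusted p = 0.00282), and ITR1, the inositol transporter gene, 1.97 ± 0.32 (adjusted p = 0.00180) and 1.67 ± 0.32 (adjusted p = 0.00420). BAR1, a protease that degrades alpha-factor, had 2.82 ± 0.92 (adjusted p = 0.00199) and 2.21 ± 0.53 (adjusted p = 0.00733). HAC1, the transcription factor of the unfolded protein response, had 1.51 ± 0.61 (adjusted p = 0.00518) and 1.99 ± 0.20 (adjusted p = 0.00366), and PDI1, which forms disulfide bonds in the endoplasmic reticulum, 1.83 ± 0.27 (adjusted p = 0.00199) and 1.66 ± 0.38 (adjusted p = 0.00436). The 20 genes of that response did not pass for the change (adjusted p = 0.0814 and 0.599). By the ratio 4 were higher, 1 lower and 15 did not pass for Ypk1, against 3 higher, 0 lower and 17 for Ypk2. JEM1 of this list went the other way for Ypk1, at −2.68, −3.82 and −2.32 after a 0 min value of −2.56. At 0 min of the Ypk2 series, over 0.5 of the later ratio was already there for PDI1 (1.53), CIT2 (1.46), PDR5 (1.23) and ITR1 (1.08), and the Ypk2 change of CIT2 was 1.19 (adjusted p = 0.987). ORM2 had 1.70 ± 0.70 (adjusted p = 0.00466) and 1.91 ± 0.26 (adjusted p = 0.00584), while the 30 measured sphingolipid genes did not pass for the change (adjusted p = 0.734 and 0.997), nor did the 26 ergosterol genes (adjusted p = 0.370 and 0.874). Calls for Ypk2 numbered 756 without 15 min, 0 without 30 min and 0 without 60 min.

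LEU2, the marker selected by growth without leucine, was higher in AS than in WT cells at 0 min, at 1.44 and 1.45, and its ratios after inhibitor were 1.60 ± 0.56 (SD, n = 3) for Ypk1 and 1.36 ± 0.13 for Ypk2. On the WT array it stood at 2.46, among the 8 highest genes, although that array holds no AS cells. Without dye swaps, a dye effect on LEU2 cannot be told apart from a difference between strains.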
